A study of Mus musculus with 6 samples.

How the data were processed

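RNA of donor-derived LSK cells from 6 samples was profiled, 3 from WT and 3 from ICAM-1-/- recipients; groups and replicate numbers were taken from the sample titles, and the series design text states 3 recipients per group and the interval of 8 weeks. Total RNA was extracted with Trizol and libraries were made with the Illumina TruSeq RNA kit, per the labels' protocols. The authors deposited gene-level FPKM values, fragments scaled by transcript length and library total, with 1 column per library. Cutadapt, TopHat2 2.0.11 and Cufflinks 2.1.1 are named in the submitters' processing notes. The genome build, annotation and any filter are not given in the sources used here, so no coordinates are printed. All 6 columns were matched to samples through their labels, and no symbol occurred more than once.

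FPKM values are model-based estimates that keep no read counts. Each library held between 24 and 111 positive values under 0.001 FPKM, which whole reads could not give, so counts were not recovered and depth is unknown. The number of genes at 1 FPKM or more ranged from 5845 in WT replicate 1 to 10864 in ICAM-1-/- replicate 3. No library pair shared values in a way that would mark a library deposited more than once.

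Values were analysed as log2(FPKM + 1) for genes with a mean of at least 1 FPKM over the 6 libraries (10477 genes) with limma 3.58.1 in R 4.3.3: a linear model with group as the only term, moderated tests with a mean-variance trend, and Benjamini-Hochberg adjustment at 0.05. Differences are ICAM-1-/- minus WT on the log2(FPKM + 1) scale, which understates changes of low genes. The median difference of all tested genes was 0.08. For 31 gene lists, camera with a preset inter-gene correlation of 0.01 was run and adjusted over the lists, for lists with at least 5 tested members; fry was run beside it. Camera's direction is relative to the other genes, so it can differ in sign from a list's median or mean: camera gave lower and the median was above 0 for the G1/S, erythroid, interferon, NF-kB, apoptosis and G1 cyclin lists, and camera gave higher with a median below 0 for the G2/M list. The means of the long-term stem cell and TGF-beta lists were above 0 and their medians below.

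Genes named in the text followed a rule: up to 12 genes per direction past the threshold, or, where fewer than 5 passed, the 5 of smallest p in that direction, leaving out clone-like names and small RNA genes; Icam1; and up to 4 members per list, of smallest p. Scarna2, Gapdh, Mpo, Ifi203, the macrophage genes, the neighbours of Ifi202b and Icam1, and the genes called under the block were named after their values were seen. Eif2s3y, a member of the sex-linked list, was named beside the 4 members that the rule gives. Some genes that the rule names are not reported here. The design, the lists, the rule and the alternatives were fixed before the data were examined, except for 4 alternatives added later: the 4 libraries of replicates 2 and 3, a batch term for the replicate 1 libraries, values under 0.001 FPKM treated as missing, and an exact sign-flip test of Icam1 over same-numbered pairs.

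Both groups carry replicate numbers 1 to 3. Deviations from the group means correlated at 0.35, 0.13 and 0.31 between libraries of the same number, all above 0.1, so the numbers were treated as pairing the samples and the fit with the replicate number as a block is given where it changed a call. WT replicate 2 also correlated at 0.31 with ICAM-1-/- replicate 3, and WT replicate 3 at 0.15 with ICAM-1-/- replicate 2. The numbers 2 and 3 were thus not told apart by this check. The pairing was inferred from the data, and the check set same-numbered libraries apart for replicate 1 only.

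The test was tested on simulated data made from the observed gene means and spreads, with 200 changed genes. With the spread of all 6 libraries 1 unchanged gene was called. A simulated list shifted by 1 log2 unit passed camera's test at 0.05 and an unshifted list did not. The simulated genes were drawn independently of each other. In the data the estimated inter-gene correlation was 0.55 for the oxidative phosphorylation list and 0.26 for the lymphoid priming list. The simulation therefore does not show how camera with the preset correlation behaves on such lists. Transcript length and the share of 31-mers found in other genes were taken from GENCODE M21 transcripts by gene symbol, and matched 90.7% of tested genes. Gene order came from the same annotation on GRCm38 and served only to find neighbours. Alternatives covered the pseudocount (0.1 and 0.5 FPKM), the filter, scaling, the trend, library weights, the block, small RNA genes, the adjusted p threshold, and leaving out each library.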

Results

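Transcriptomes were measured by RNA sequencing in LSK cells, the lineage-negative, Sca-1-positive, c-Kit-positive bone marrow fraction that holds hematopoietic stem cells and multipotent progenitors. Wild-type donor cells carrying the Ly5.1 allele of CD45 had been transplanted into Ly5.2 recipients that were either wild type (3 libraries) or ICAM-1-/- (3 libraries), and were sorted again 8 weeks later. ICAM-1 is an endothelial and stromal adhesion molecule that binds leukocyte integrins. The study asked about stem cell quiescence and repopulation in a niche without ICAM-1, and the comparison here is of donor cells from both kinds of recipient. The deposited values were FPKM for 23228 genes. They carry no read depth, so the counting error behind a value is unknown.

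The 6 libraries were uneven. WT replicate 1 listed 16716 genes at 0, against 10167 and 10525 in WT replicates 2 and 3. The ICAM-1-/- libraries listed 12990, 12908 and 9308 genes at 0 in replicates 1, 2 and 3. Scarna2, a small Cajal body RNA, made up 63.9% of all FPKM in WT replicate 1 and 43.1% in ICAM-1-/- replicate 1. Of 4377 genes with a mean of at least 10 FPKM, 1007 were listed at 0 in WT replicate 1 and 221 in ICAM-1-/- replicate 1, against 16 to 87 in the other 4 libraries. These included Gapdh, a glycolytic enzyme used by every cell, at 0 in WT replicate 1 and 8.94 FPKM in ICAM-1-/- replicate 1, against 407 to 909 FPKM elsewhere. A value of 0 in these data is therefore reported only as listed at 0.

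Replicate 1 of both groups also differed from the other libraries in sex-linked transcripts. Xist, the RNA that silences the inactive X chromosome, stood at 241 FPKM in WT replicate 1 and 73.5 FPKM in ICAM-1-/- replicate 1, and at 0.0487 to 0.153 FPKM in the other 4. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0 in both replicate 1 libraries and were above 0 in the other 4. Ddx3y, for example, ranged from 2.30 to 12.3 FPKM there. On the log2 scale WT replicates 2 and 3 correlated across tested genes at r = 0.92, while WT replicate 1 correlated with them at 0.38 and 0.35. ICAM-1-/- replicate 3 correlated with WT replicates 2 and 3 at 0.93 and 0.91. ICAM-1-/- replicate 2 correlated with these libraries at 0.77 to 0.78 and ICAM-1-/- replicate 1 at 0.62 to 0.64. The replicate 1 libraries correlated with each other at 0.48. The subset of replicates 2 and 3 thus still holds a library, ICAM-1-/- replicate 2, that lies apart from the rest. Genes are not independent replicates in these correlations. Comparisons are given below over all 6 libraries, with values within replicates 2 and 3 for the results that moved most. The 2 replicate 1 libraries alone leave 1 per group and give no test.

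**Figure D1:**
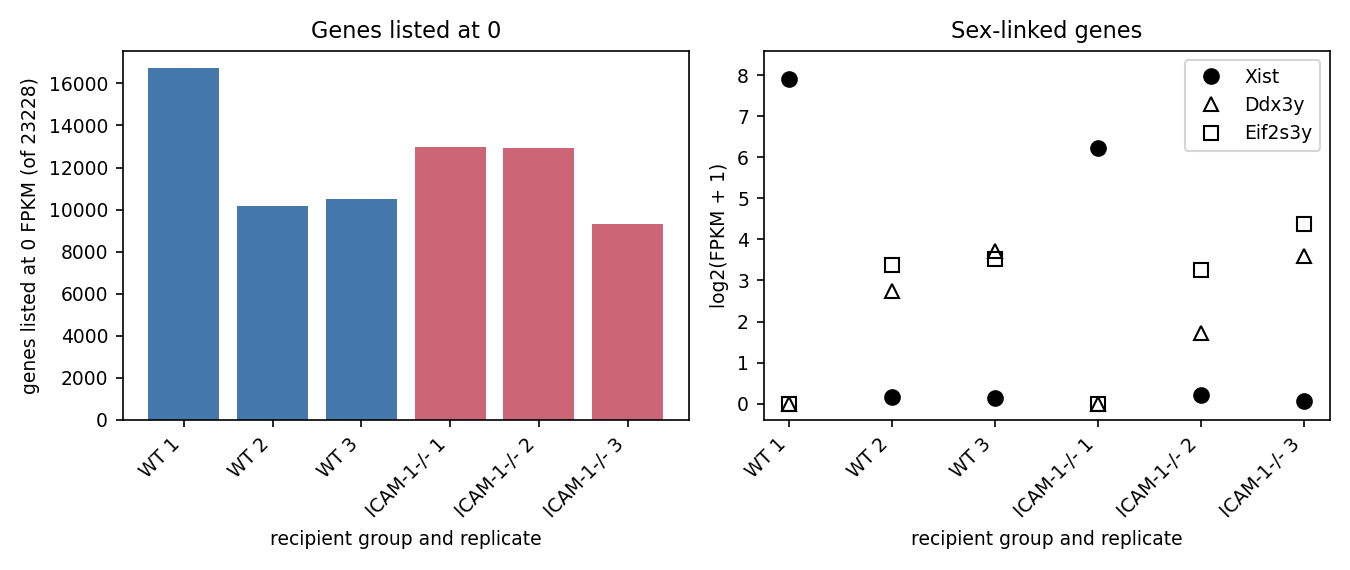
Left, bars give the number of genes listed at 0 FPKM in each library, blue for WT and red for ICAM-1-/- recipients. Right, points give log2(FPKM + 1) of Xist (filled circles), Ddx3y (triangles) and Eif2s3y (squares) per library; Xist is high and both Y-linked genes are at 0 in replicate 1 of each group.

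Icam1, the gene deleted in the ICAM-1-/- recipients, had transcripts in the libraries of both groups. Its level was 14.5 ± 10.3 FPKM (SD, n = 3) in WT recipients and 19.1 ± 11.4 FPKM (SD, n = 3) in ICAM-1-/- recipients. The values were 26.4, 9.12 and 7.97 FPKM in WT replicates 1 to 3 and 32.1, 10.9 and 14.1 FPKM in ICAM-1-/- replicates 1 to 3. The difference of 0.42 ± 0.81 (SE) on the log2(FPKM + 1) scale did not pass the limma test (adjusted p = 1.00), and an exact two-sided permutation test gave p = 0.5, where 0.1 is the smallest value 3 against 3 libraries allow. Icam1 was higher in the ICAM-1-/- library in 3 of 3 same-numbered pairs, for which an exact two-sided sign-flip test gave p = 0.25, the smallest it allows. The samples carry the genotype of the recipient in their labels while the donor cells were wild type. Icam1 was above 0 in every library, and whether a deletion allele leaves a transcript was not examined. Which of the sorted cells made the transcript was not examined either.

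No gene passed an adjusted p of 0.05 between donor cells from ICAM-1-/- and WT recipients. Of 10477 genes tested with limma, 54 had an unadjusted p under 0.05, 44 of them higher and 10 lower in ICAM-1-/- recipients, where 524 would be expected by chance among independent, unpaired libraries. With the replicate number as a block, 278 genes had an unadjusted p under 0.05. The groups did not overlap for 427 genes, or 4.08%, where chance gives 10% for unpaired libraries without tied values. Genes tied at 0 in most libraries, such as Snord85, cannot part the groups, so the chance share here lies below 10%. The median within-group SD was 1.09 on the log2 scale with all 6 libraries and 0.835 within replicates 2 and 3. In simulated unpaired data with the observed spread of these 10477 genes, the same test recovered 0 of 50 genes changed by 2 log2 units, 18% of those changed by 4 and 54% of those changed by 6. With the spread of replicates 2 and 3 in simulated groups of 3, it recovered 10%, 60% and 90%.

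Ifi202b had the smallest p of all genes. This interferon-inducible gene of the Ifi200 family was listed at 0 in all 3 WT libraries and stood at 29.0, 96.3 and 53.5 FPKM in ICAM-1-/- replicates 1, 2 and 3 (limma adjusted p = 0.304). With the replicate number as a block it passed the test (limma adjusted p = 0.000619), as it did within replicates 2 and 3 (limma adjusted p = 1.30e-05). Ifi203, another member of the family, stood at 0, 12.3 and 17.2 FPKM in WT replicates 1 to 3 and at 4.50, 3.33 and 16.5 FPKM in ICAM-1-/- replicates 1 to 3.

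The other genes of smallest p on the higher side did not pass the test, with adjusted p of 1.00 each in limma. Fcer1g, the common signalling chain of Fc receptors, stood at 0, 52.5 and 9.78 FPKM in WT replicates 1 to 3 and at 66.3, 311 and 117 FPKM in ICAM-1-/- replicates 1 to 3, a log2 difference of 4.02 ± 1.26 (SE). It passed with the block (limma adjusted p = 0.00334) and within replicates 2 and 3 (limma adjusted p = 0.0446). Dcun1d5, which takes part in cullin neddylation, had a log2 difference of 3.37 ± 1.06. Serpina3g, a serine protease inhibitor of hematopoietic cells, stood at 0.0223, 11.8 and 14.2 FPKM in WT and at 67.1, 41.5 and 52.2 FPKM in ICAM-1-/- replicates 1 to 3, a log2 difference of 3.20 ± 1.03. Slpi, a secreted inhibitor of leukocyte proteases, had a log2 difference of 3.39 ± 1.17. For Fcer1g, Dcun1d5 and Slpi the WT replicate 1 value was listed at 0, and within replicates 2 and 3 the log2 differences were 3.00, 2.30 and 1.67. That of Serpina3g was 1.77.

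On the lower side the genes of smallest p were Ndufb7, Ltf, Asf1a, Pdgfa and Siah1b, none of which passed (limma adjusted p = 1.00 each). Ndufb7, a subunit of mitochondrial complex I, had 96.8 ± 38.8 FPKM in WT and 29.6 ± 33.4 FPKM in ICAM-1-/- recipients (SD, n = 3), a log2 difference of -2.17 ± 0.86 (SE) and of -1.34 within replicates 2 and 3. The histone chaperone Asf1a had 31.6 ± 12.5 against 8.57 ± 4.06 FPKM (SD, n = 3), a log2 difference of -1.78 ± 0.75 and of -1.23 within replicates 2 and 3. Ltf, the neutrophil granule protein lactoferrin, stood at 25.9, 63.3 and 12.2 FPKM in WT replicates 1 to 3 and at 0, 2.22 and 18.9 FPKM in ICAM-1-/- replicates 1 to 3. The growth factor gene Pdgfa and the ubiquitin ligase gene Siah1b were each listed at 0 in ICAM-1-/- replicates 1 and 2.

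**Figure D2:**
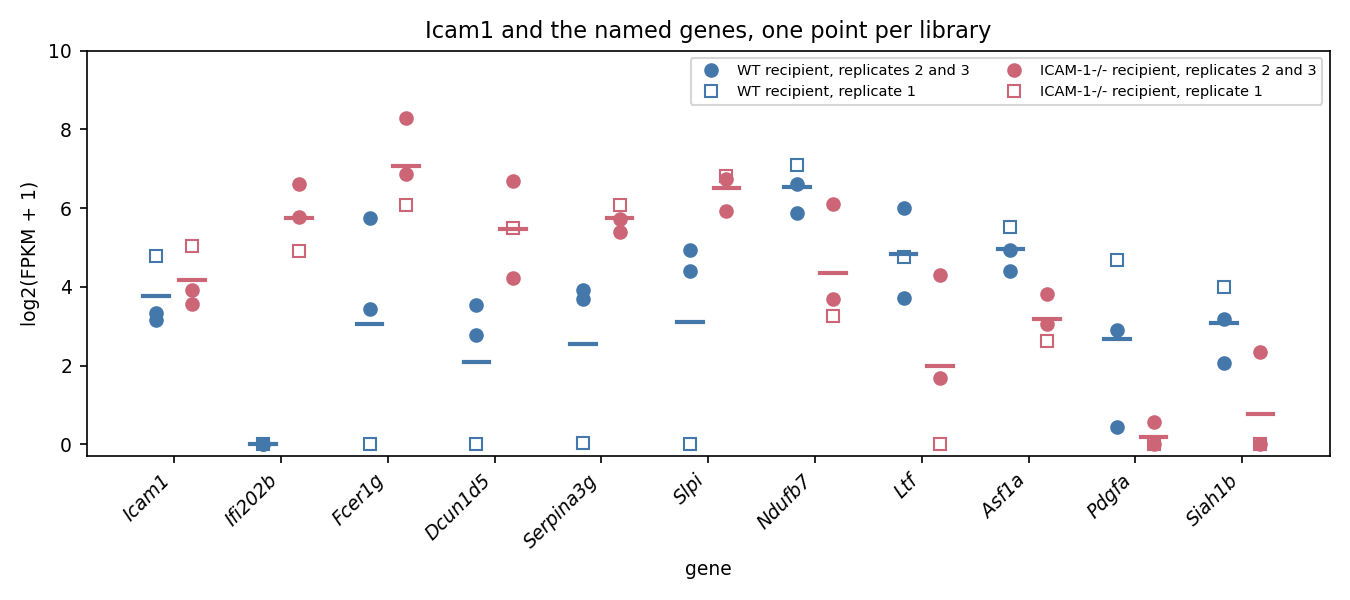
Each point is log2(FPKM + 1) of a gene in a library, blue for WT and red for ICAM-1-/- recipients; open squares are replicate 1, filled circles replicates 2 and 3, and bars the group mean. Ifi202b is at 0 in the 3 WT libraries and above 0 in the 3 ICAM-1-/- libraries, and Icam1 overlaps between groups.

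With the replicate number as a block, limma called 13 genes, 11 higher and 2 lower in ICAM-1-/- recipients. Of these, 6 were small nucleolar RNA or microRNA genes: Snord34, Snord22, Snora78, Snord85 and Mir703 higher, Mir5109 lower. The remaining calls were Ifi202b, Fcer1g, Gm15772, Hist1h2bm, Rps20 and Shfm1 on the higher side and 1810006K21Rik on the lower. Snord85 was called although it was above 0 in a single library, at 25296 FPKM in ICAM-1-/- replicate 3, and Rps20, Hist1h2bm and Shfm1 were listed at 0 in WT replicate 1 alone. In this fit limma estimated an infinite prior df, so that a gene's own spread did not enter its p. Within replicates 2 and 3 the same was true, and 18 genes were called, 10 higher and 8 lower, 12 of them small RNA genes. The 2 sets shared 9 genes.

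No stem cell gene passed the test. None of 23 tested members of the long-term stem cell identity list passed, 11 having positive and 12 negative log2 differences (median -0.03, camera adjusted p = 0.922). Ly6a, which encodes the Sca-1 antigen used in the sort, stood at 0, 20.8 and 57.7 FPKM in WT and 34.3, 12.4 and 91.8 FPKM in ICAM-1-/- replicates 1 to 3. Ifitm1, an interferon-induced membrane protein, had a log2 difference of 2.52 ± 1.62 (SE) with WT replicate 1 listed at 0, and one of -0.21 within replicates 2 and 3. None of 22 quiescence regulators passed (median -0.23, camera adjusted p = 0.414). Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, had a log2 difference of 1.41 ± 1.21 with WT replicate 1 listed at 0, and one of 0.09 within replicates 2 and 3. Nr4a1, an orphan nuclear receptor, had one of 0.84 ± 0.71. In no list did a member pass when adjusted over the list alone.

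Cell cycle genes likewise gave no call. All 44 G1/S genes and all 50 G2/M genes were tested and none passed, with medians of 0.05 and -0.01 (camera adjusted p = 0.770 and 0.996). Within replicates 2 and 3 their medians were -0.35 and -0.40, with 35 of 44 and 38 of 50 genes below 0 (camera adjusted p = 0.714 and 0.570), where the median of all genes was -0.32. The replication factor Cdc45 had a log2 difference of 2.41 ± 1.12, with WT replicate 1 listed at 0, and cyclin E2 (Ccne2) of -2.11 ± 1.03. These were 0.83 and -1.44 within replicates 2 and 3. The list of G1 cyclins and kinases had a median of 0.12 (camera adjusted p = 0.780). Among integrins, selectin ligands and homing receptors, none of 33 passed (median 0.06, camera adjusted p = 0.996). Icam2, another integrin ligand, had a log2 difference of 2.33 ± 1.07, with WT replicate 1 listed at 0, and of 1.64 within replicates 2 and 3.

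The multipotent progenitor and lymphoid priming list was lower in ICAM-1-/- recipients by camera with a preset correlation (adjusted p = 0.0261; adjusted p = 0.999 with an estimated correlation). None of its 21 members passed singly, over all genes or adjusted over the list alone; 13 had negative and 8 positive log2 differences, with a median of -0.47. The lymphoid genes Rag1, a recombinase, and Satb1, a chromatin organizer, had log2 differences of -1.53 ± 0.84 and -1.48 ± 0.90 (SE). Il12a, a cytokine subunit, had -2.02 ± 1.06 with ICAM-1-/- replicate 1 listed at 0, whereas Cd34 had 2.27 ± 1.48 with WT replicate 1 at 0.0203 FPKM. Il12a had -0.55 and Cd34 had 0.46 within replicates 2 and 3. The call was also lost with the replicate block (adjusted p = 0.0511), with a pseudocount of 0.1 (0.0568) and with near-zero values as missing (0.110). The adjusted p was 0.366 without WT replicate 2, 0.10 without WT replicate 3 and 0.139 without ICAM-1-/- replicate 1. By contrast, the list stayed called lower without WT replicate 1 (camera adjusted p = 4.90e-05), ICAM-1-/- replicate 2 (0.00279) or ICAM-1-/- replicate 3 (0.0358). It also stayed called lower with library weights (camera adjusted p = 4.79e-06). Within replicates 2 and 3, 18 of 21 members were lower (camera adjusted p = 0.00834; 0.988 with an estimated correlation), while the median of all genes there was -0.32. The mean log2 level of the list there was 4.89 and 4.42 in WT and 3.08 and 4.53 in ICAM-1-/- replicates 2 and 3. In this subset ICAM-1-/- replicate 2 lay below both WT libraries, as it did for every other list, and ICAM-1-/- replicate 3 did not. Leaving ICAM-1-/- replicate 2 out of the 6 libraries nevertheless kept the list lower, as given above.

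The granulocyte and monocyte priming list had a median of 0.71 over all libraries and did not pass (camera adjusted p = 0.262). Within replicates 2 and 3 it was lower, with 17 of 19 members below 0 and a median of -0.72 (camera adjusted p = 0.0160; 0.988 with an estimated correlation). The median of all genes there was -0.32. The mean log2 level of the priming list there was 6.66 and 6.43 in WT and 5.01 and 6.80 in ICAM-1-/- replicates 2 and 3. ICAM-1-/- replicate 2 alone lay below WT. It lay below both WT libraries for every other list as well, so its low level was not particular to this list. The list was called higher without WT replicate 2 (camera adjusted p = 0.0316) and without WT replicate 3 (camera adjusted p = 0.0358). Mpo, the myeloperoxidase of granule-forming progenitors, stood at 311, 764 and 726 FPKM in WT and at 2326, 158 and 783 FPKM in ICAM-1-/- replicates 1 to 3. The megakaryocyte and erythroid lists did not pass (camera adjusted p = 0.674 and 0.860).

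The oxidative phosphorylation list was the other call, higher in ICAM-1-/- recipients by camera (adjusted p = 0.0260; adjusted p = 0.999 with an estimated correlation). Of 58 members 43 had positive and 15 negative log2 differences (median 0.55), and none passed singly, over all genes or adjusted over the list alone. Cox7a2, a cytochrome oxidase subunit, and Ndufb2, a subunit of complex I, had log2 differences of 3.11 ± 1.35 and 2.88 ± 1.24 (SE). Cox7a2 was at 0.0556 FPKM and Ndufb2 listed at 0 in WT replicate 1, and within replicates 2 and 3 the log2 differences were 1.10 and 1.14. The call was also lost with no filter on low values (0.0599), and without ICAM-1-/- replicate 2 (0.311) or 3 (0.330). The mean log2 level of the list was 2.33 in WT replicate 1, against 6.11 and 6.15 in WT replicates 2 and 3 and 4.96, 5.14 and 6.67 in ICAM-1-/- replicates 1 to 3. Without WT replicate 1 camera's direction was lower (adjusted p = 0.120). Within replicates 2 and 3 no direction was called (adjusted p = 0.951), and the list's median of -0.20 lay above that of all genes, -0.32.

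Cytosolic ribosomal protein genes followed the replicate 1 libraries more than the groups. Their mean log2 level was 2.53 in WT replicate 1 and 3.91 in ICAM-1-/- replicate 1, and 8.68 to 9.80 in the other 4. Over all libraries the list did not pass (median 0.35, camera adjusted p = 0.409). With camera it was higher with the replicate block (adjusted p = 0.000111) and within replicates 2 and 3 (adjusted p = 0.0160; 0.988 with an estimated correlation), where 43 of 78 members were above 0, and lower without WT replicate 1 (adjusted p = 1.11e-14) or ICAM-1-/- replicate 2 (adjusted p = 0.00224). It was also higher without WT replicate 2 (3.18e-08), WT replicate 3 (4.56e-09) or ICAM-1-/- replicate 1 (1.87e-21), so that the library left out set the direction of its call. Lists of glycolysis and HIF targets, reactive oxygen defence, and Myc targets and ribosome biogenesis had medians of 0.43, 0.60 and 0.43 and did not pass (camera adjusted p = 0.674, 0.119 and 0.119). Their medians were -0.11, -0.26 and -0.11 within replicates 2 and 3. Myc targets were called higher under median-of-ratios scaling (camera adjusted p = 0.0445), with near-zero values as missing (0.0141) and without WT replicate 3 (0.0358) or ICAM-1-/- replicate 2 (0.0126).

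Signalling and stress lists gave no call over the 6 libraries at the main settings. The type I interferon list had a median of 0.07 over 32 members (camera adjusted p = 0.852), with Ifi27l2a at 1.87 ± 1.18 (SE), and at 0.05 within replicates 2 and 3, and Mx2, an antiviral GTPase, at -1.46 ± 1.01. The NF-kB and inflammatory list, the TGF-beta response and the immediate early genes had adjusted p of 0.930, 0.996 and 0.763 by camera. The Notch and Wnt list had 12 of 16 members below 0 (median -0.38, camera adjusted p = 0.119), and was called lower under median-of-ratios scaling (camera adjusted p = 0.0460). All 16 were below 0 within replicates 2 and 3 without a call (median -0.58, camera adjusted p = 0.381), where the median of all genes was -0.32. The list's mean log2 levels there were 2.77 and 2.57 in WT and 1.32 and 2.90 in ICAM-1-/- replicates 2 and 3. The heat shock and unfolded protein list had 20 of 25 members above 0 (median 0.35, camera adjusted p = 0.262), and was called higher within replicates 2 and 3 (camera adjusted p = 0.0458; 0.988 with an estimated correlation), where 12 of its 24 members were above 0. Over all 6 libraries it was called higher under median-of-ratios scaling (camera adjusted p = 0.0460), library weights (0.000138) and near-zero values as missing (0.0243). The p53 target, apoptosis and autophagy lists had adjusted p of 0.401, 0.996 and 0.674.

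Markers of mature cells that a sort could carry over were examined beside these lists. The neutrophil list was not called over all libraries (median -0.18, camera adjusted p = 0.119). It was called lower with a filter of mean FPKM of at least 5 (camera adjusted p = 0.0205), with a batch term for replicate 1 (0.0223), with library weights (2.34e-05), and without WT replicate 1 (1.81e-07), WT replicate 3 (0.0432) or ICAM-1-/- replicate 3 (0.00717). It was also lower with the replicate block (camera adjusted p = 0.000946) and within replicates 2 and 3, where all 17 members were below 0 (median -0.81, camera adjusted p = 6.14e-05; 0.988 with an estimated correlation). The median of all genes there was -0.32. The mean log2 level of the neutrophil list there was 5.15 and 3.68 in WT and 2.36 and 4.44 in ICAM-1-/- replicates 2 and 3. ICAM-1-/- replicate 2 lay below both WT libraries, as it did for every other list. S100a8, an abundant neutrophil calcium-binding protein, stood at 415, 693 and 279 FPKM in WT and at 135, 14.5 and 608 FPKM in ICAM-1-/- replicates 1 to 3. The B cell list had 9 of 11 members below 0 (camera adjusted p = 0.243), and was called lower with library weights (8.61e-07) and without WT replicate 1 (0.00521) or ICAM-1-/- replicate 2 (0.0315). The monocyte, macrophage and dendritic list had a median of -0.25 (camera adjusted p = 0.674), with mean log2 levels of 5.48 and 4.96 in WT and ICAM-1-/- replicate 1 and 2.53 to 4.05 in the other 4 libraries. The T and NK cell, basophil and mast cell, stromal and endothelial, and sex-linked lists did not pass (camera adjusted p = 0.674, 0.625, 0.510 and 0.674).

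**Figure D3:**
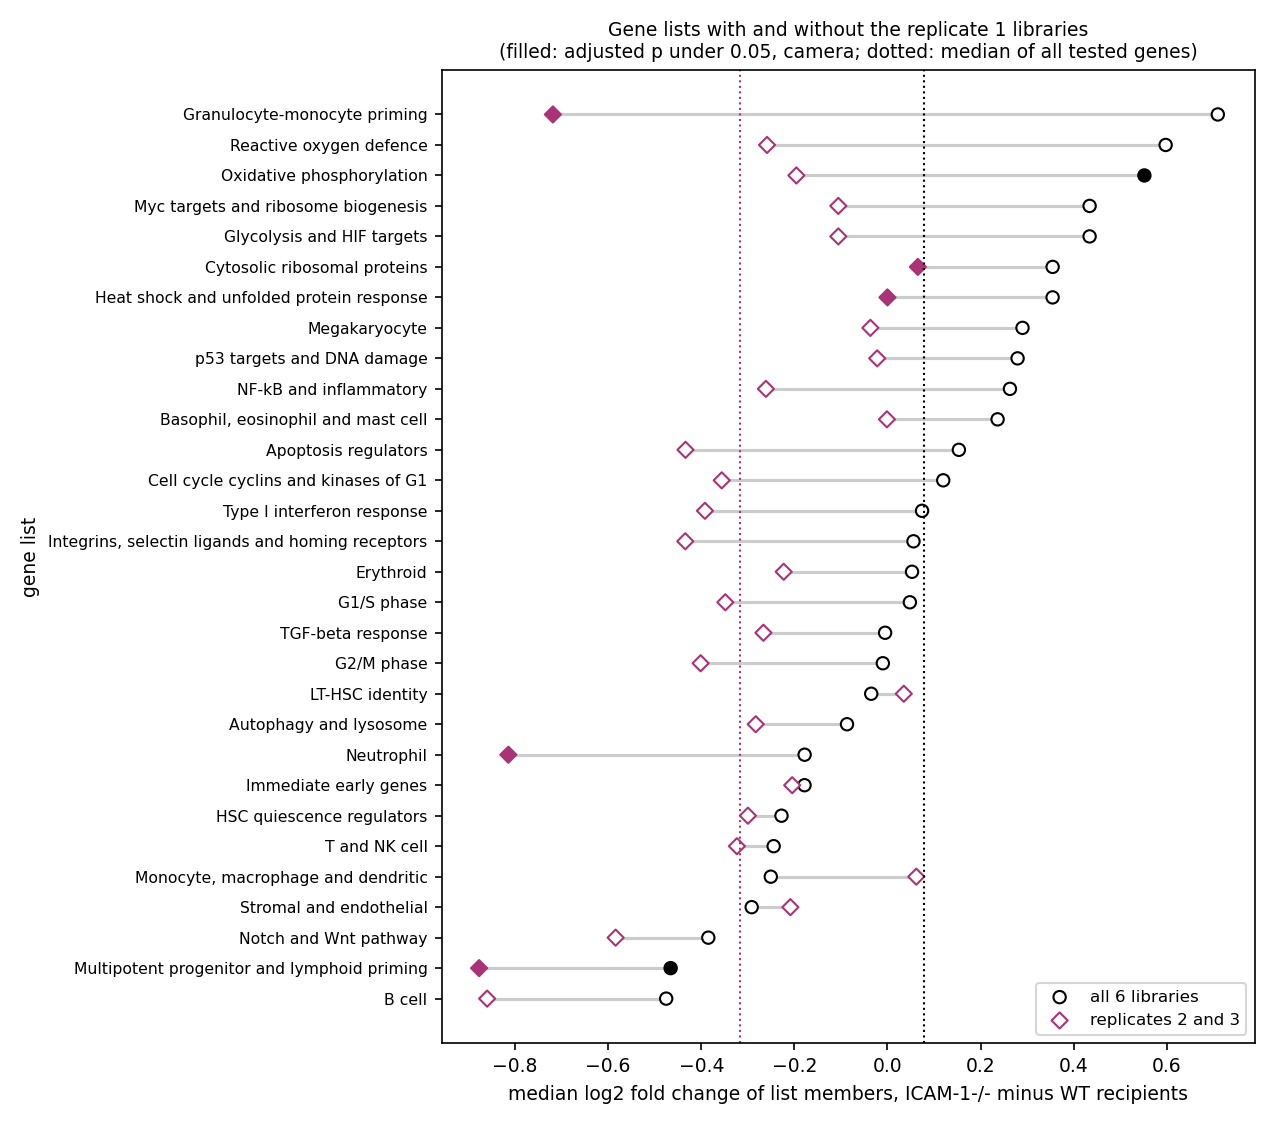
Each row is a gene list; circles give the median log2 difference of its members (ICAM-1-/- minus WT recipients) over all 6 libraries and diamonds within replicates 2 and 3, filled where camera's adjusted p was under 0.05, with dotted lines at the median of all tested genes (0.08 and -0.32). The oxidative phosphorylation median moves from 0.55 to -0.20 without the replicate 1 libraries, and the lymphoid priming median stays below 0; the sex-linked list had too few tested members within replicates 2 and 3 and is left out.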

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

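The choices were made before the data were examined, except for the subset of replicates 2 and 3, the batch term for the replicate 1 libraries, near-zero values as missing, and the paired test of Icam1, which were chosen after seeing the data. The count of called genes was 0 and stayed 0 with limma under both other pseudocounts, both other filters, quantile and median-of-ratios scaling, no mean-variance trend, an adjusted p threshold of 0.1, without small RNA genes, and with near-zero values as missing. It was 4 with library weights, 13 with the replicate block, 18 within replicates 2 and 3, 1 with the batch term (Ifi202b), and 0 to 2 when a library was left out. Groups did not overlap for 427 genes, a count with no threshold on p. The adjusted p of Ifi202b ranged from 1.30e-05 to 1.00 and passed in 5 of 19 alternatives. Icam1 passed in none of 20, with log2 differences from -0.01 to 0.93. The number of called lists was 2, and became 1 with a pseudocount of 0.1 or no filter, 3 with a filter of mean FPKM of at least 5 or the replicate block, 5 with median-of-ratios scaling or within replicates 2 and 3, 7 with library weights, 4 with the batch term or near-zero values as missing, 0 with an estimated correlation or fry, and 2 to 8 when a library was left out. With library weights the monocyte, macrophage and dendritic and the immediate early lists turned higher (adjusted p = 0.00324 and 0.00567), and oxidative phosphorylation and cytosolic ribosomal proteins lower (0.439 and 2.14e-12). Within replicates 2 and 3 granulocyte-monocyte priming turned lower (0.0160), and camera's sign for oxidative phosphorylation was lower without a call (0.951). Without WT replicate 1 the monocyte and immediate early lists turned higher and oxidative phosphorylation and ribosomal proteins lower, and without ICAM-1-/- replicate 2 ribosomal proteins turned lower. The monocyte list was instead called lower without WT replicate 3 (0.00154) or ICAM-1-/- replicate 1 (0.0360), and immediate early genes without WT replicate 2 (0.0316) or ICAM-1-/- replicate 1 (0.0209). Ribosomal proteins were called higher with the batch term (0.00182) and near-zero values as missing (0.0243). Over the libraries left out, adjusted p ranged from 1.44e-05 to 0.935 for the monocyte list, 0.000471 to 0.930 for immediate early genes, 3.54e-08 to 0.330 for oxidative phosphorylation and 1.87e-21 to 0.649 for ribosomal proteins. Heat shock was called without WT replicate 1 (0.000343) or ICAM-1-/- replicate 2 (0.0315), reactive oxygen defence without WT replicate 2 (0.0316) or 3 (0.0358), and Notch and Wnt without WT replicate 3 (0.0358) or ICAM-1-/- replicate 1 (0.0107). The cause was not tested. Of 2478 values of named genes 72 changed sign, and of 613 list values 90 changed direction, 11 of them with a call on either side. The 10 genes of smallest p kept their sign wherever tested. The median of all tested genes was 0.08, and moved to 0.24 with median-of-ratios scaling, -0.05 with quantile normalization, 0.28 with library weights and -0.32 within replicates 2 and 3. No symbol was repeated, so summing rows changed nothing. The block changed no call other than those given with the results. Depth is unknown, so counting error could not be set against these differences.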

Other observations

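Transcripts of bone marrow macrophages stood high in replicate 1 of both groups, a pattern outside the comparison of recipients, in genes chosen after their values were seen. Vcam1, an adhesion molecule, stood at 449 and 146 FPKM in WT and ICAM-1-/- replicate 1 and at 1.78 to 15.1 FPKM in the other 4 libraries. Hmox1, the inducible heme oxygenase, stood at 347 and 195 FPKM against 3.50 to 19.6 FPKM. Slc40a1, the iron exporter ferroportin, stood at 276 and 87.2 FPKM against 1.36 to 13.0 FPKM, and the complement gene C1qb at 570 and 258 FPKM against 4.59 to 40.7 FPKM. Immediate early genes stood higher there too, with median log2 differences between replicate 1 and the mean of replicates 2 and 3 of 1.63 in WT and 1.41 in ICAM-1-/- recipients, against -0.82 and 0.45 for all tested genes.

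The tests of macrophage RNA, the interferon response, paralogs, the weight of WT replicate 1 and other splits were chosen after the result was seen, as were the bootstrap interval and the size of the windows compared with that of Icam1. The first pattern is that the replicate 1 libraries stand apart: among genes with a mean of at least 10 FPKM, those with at least 20% of their 31-mers in other genes were under 0.001 FPKM in 47.0% of cases in WT replicate 1 and 19.7% in ICAM-1-/- replicate 1, against 17.8% and 1.97% of genes with under 1% shared, ratios of at least 2.64 (Fisher's exact test p = 1.04e-45 and 9.82e-50). Among the genes with little sharing, 61.4% and 15.8% of transcripts under 1 kb were that low, against 8.11% and 0.294% of those over 2 kb, ratios of at least 7.573. In the other 4 libraries the shares were lower, 1.2% to 3.95% for shared and 3.51% to 12.3% for short genes. The ratios there were 2.64 to 5.08 for shared and 23.2 or more for short genes, so both may be general traits of the quantification. In ICAM-1-/- replicate 1 the ratio for shared genes (19.7% against 1.97%) lay above their range, and that for short genes lay within it. Neither ratio was raised in WT replicate 1 over those libraries, but its ratios had little room to rise. There 17.8% of genes with little sharing and 8.11% of long genes were already near 0, which caps a ratio. The ratio for short genes could not have reached 23.2. The ratio for shared genes thus sets ICAM-1-/- replicate 1 apart, and the ratios cannot decide for WT replicate 1. The shares of shared and short genes near 0 there, 47.0% and 61.4%, lay above those of the other 4 libraries. The monocyte, macrophage and dendritic list had median differences of 2.39 in WT and 1.63 in ICAM-1-/- recipients, above all tested genes by at least 1.174, and the 9 tested stromal and endothelial genes 2.58 and 0.95, so RNA from macrophages could contribute but other marrow cells are not excluded; the sort took lineage-negative cells, and 22 genes of the former list also passed the filter within replicates 2 and 3. Xist and the Y-linked genes part the replicate 1 libraries from the other 4, as RNA of female and of male cells would. Whether sex or a separate batch accounts for the other differences stays open and untested. No biological explanation was tested because the design names none for a replicate number.

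The second pattern is Ifi202b, listed at 0 in the 3 WT libraries and above 0 in the 3 ICAM-1-/- libraries. Of the Ifi202b 31-mers, 1.2% occur in other GENCODE M21 genes, so exact sharing within that annotation was rare. Copies that differ from the annotation were not covered by this count, so reads from paralogs were not excluded. The interferon list showed no upward shift, its median within replicates 2 and 3 lying -0.07546 log2 units from that of all genes. Its bootstrap 95% interval of -0.16 to 0.11 resampled member genes and holds no spread between libraries. The list's mean log2 levels were 2.68 and 2.56 in WT and 1.43 and 3.06 in ICAM-1-/- replicates 2 and 3. With 2 libraries per group so far apart, a broad interferon response could not be decided. A candidate explanation is a strain haplotype on chromosome 1. The 100 tested genes nearest to Ifi202b were taken, leaving out neighbours noticed beforehand. Of these, 4% (Dusp12, Itln1, Cd48 and Nenf) had an unadjusted limma p under 0.05 within replicates 2 and 3. That was more than in 97.1% of windows of that size, whose median was 1%. The windows overlap, and in this fit a gene's own spread did not enter its p, so the percentile is no significance level. Around Icam1 on chromosome 9 the share was 2.174% of 92 genes (Dcun1d5 and Taf1d), above 72.2% of windows. These were too few genes to decide whether DNA flanking the deleted gene is present. Both groups hold wild-type donor cells by design, so a haplotype difference would mean that the sorted cells differ in genotype or are not all donor-derived, which would bear on every difference between the groups; it remains a hypothesis, and an effect of the recipients on the donor cells stays open and untested.

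The third pattern is the higher oxidative phosphorylation list. Without WT replicate 1 its median lay -0.08572 log2 units from that of all tested genes, so that library may set the direction. Its median t of 0.55 was above that of 94.57% of 10000 random lists matched on transcript length, whose median was 0.30. That lies within their central 95%, so gene length was not excluded as a source. Lists not matched on length were not drawn, so a contribution of length was not shown either. An effect of the recipients was not separated from these.

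The 6 libraries allow 10 splits of 3 against 3, too few for a share under 0.05. The real split called 0 genes, which 10 of 10 splits match by definition, and the highest other split called 4. For lists, the real split called 2 and the highest other split 8, with 9 of 10 calling as many. The 4 splits with both replicate 1 libraries on the same side called 6 to 8 lists, against 0 to 2 in the 6 splits that part them, which points to a structure of the samples by replicate 1. Genes at an unadjusted p under 0.05 did not separate these splits, with 371 to 1332 when together and 54 to 792 when parted, 54 being the real split. Of the splits that part all 3 same-numbered pairs, the other 3 also called 0 genes and 2 lists each, with 105, 792 and 104 genes at an unadjusted p under 0.05.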
